A study of Caenorhabditis elegans with 2 samples.

How the data were processed

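Chromatin from whole L4 larvae of a strain with EGFP-tagged lin-13 was immunoprecipitated and sequenced in 2 biological replicates, with fragments of 150 to 350 bp per the labels. Both replicates formed 1 group, taken from the labels' descriptions and replicate numbers.

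The authors deposited narrowPeak lists on builds ce11 and ce10. Per the deposited listings that accompany them, a relaxed list was called for each replicate and for the pooled replicates with a control library, and the IDR list was derived from these. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. The signal value of a peak is the authors' caller's and was deposited without a stated scaling, so it was compared within a list or by rank, except in the correlation between replicates and in setting pooled values against the replicates' sum. The deposited −log10 q-value column reached a maximum that many peaks shared (3.17 in all 2141 IDR peaks and in 2197 pooled relaxed peaks) and was not used to rank. The IDR list was exactly the 2141 pooled peaks of highest signal value, so the peaks called were those of pooled animals and no test here measures spread between animals. Most pooled peaks had the same width of 336 bp. Depth per replicate is unknown, which leaves open how far it shaped the difference between the replicates' lists.

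Positions were taken on ce11 with the WBcel235 genome, whose soft-masked bases served as repeats, and the Ensembl annotation, release 115. Coordinates are printed counting from 1. The summit of the clec-126 peak lay 1 bp beyond the peak's end and was used as given. Annotated 5' ends are often trans-splice sites in this species, so 500 bp on either side were used. Mitochondrial peaks were left out of position, gene and motif tests.

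The tests, the 20 gene lists, the 10 motifs and the rule for named genes were fixed before the data were examined. The rule took the 10 highest peaks with the nearest protein-coding 5' end, up to 3 members per list with the highest peak, and lin-13, unc-119, lin-35, hpl-2 and lin-61. The symbols hsp-16.1 and hsp-16.48 each name 2 annotated genes, so the 28 symbols of the stress response list matched 30 genes. The symbols rad-54, rde-3, lin-4 and let-7 matched no protein-coding gene. Shares were tested with exact binomial, Fisher's or McNemar tests, two-sided, with exact Clopper-Pearson 95% intervals, which cover counting error only. Signal differences were tested with 100000 seeded permutations. Adjusted p-values are Benjamini-Hochberg values within each family, with a threshold of 0.05. Summits and genes were treated as independent, although summits cluster and 298 summits lay within reach of the 5' ends of more than 1 protein-coding gene. The p-values are too small to that extent. Reads of near-identical ribosomal protein, histone and tRNA copies may be shared.

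The steps were tested on simulated data of 2121 summits. A planted promoter share of 46.1% was estimated at 46.4% and called in 20 of 20 runs. A planted list of 36 genes was called in 19 of 20 runs and unchanged lists in 0 of 380 tests. Its planted odds exceeded the odds ratios later found for the lists called higher, ribosomal protein genes aside (4.45 to 7.19). The planted rate of 19 of 20 may therefore not hold for effects of that size or smaller. A planted motif was called in 20 of 20 runs and unplanted motifs in 1 of 180 tests. The simulated summits were independent, so these rates do not cover clustering.

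The alternatives were 1 replicate alone, a stricter list (the 1070 highest IDR peaks), a looser list (the 4282 highest pooled peaks), the ce10 files, other distances, windows and overlaps, and relaxed peaks as the background. Thinning to 1 summit per 10 kb, summits at the 5' ends of 1 protein-coding gene only and windows matched on GC content were added after seeing the data. Arms on ce10 were not run, since ce10 chromosome lengths were not used here, and the X share on ce10 was set against the ce11 share of length. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.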

Results

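The data were peak lists from chromatin immunoprecipitation sequencing of LIN-13 in whole L4 larvae of Caenorhabditis elegans. LIN-13 is a zinc-finger protein of the synMuv B class, a set of genes that restrain vulval fate. The strain carried a transgene of lin-13 fused to TY1, EGFP and FLAG tags beside the endogenous gene. There was 1 group with 2 biological replicates and no second condition, so the comparisons were between the replicates, between peak positions and the genome, and between sets of genes. Sequencing depth per replicate was unknown, because the files held no read counts. The list that passed the irreproducible discovery rate (IDR) threshold held 2141 peaks on build ce11, of which 2121 were nuclear and 20 mitochondrial. Each relaxed list, made as input for that step, held 30000 peaks.

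Peaks upstream of rpl-3, tasp-1 and cdc-48.1 had the highest signal values in the nuclear genome. The highest nuclear peak lay on chromosome III from 3867437 to 3867723 (ce11), with its summit 274 bp upstream of the 5' end of rpl-3, a large ribosomal subunit protein gene, and a signal value of 634.7. The next lay 55 bp upstream of tasp-1 (chromosome III, 10759116 to 10759382, signal value 512.9) and 171 bp upstream of cdc-48.1, which encodes a AAA ATPase (chromosome II, 10563449 to 10563693, signal value 412.1). Peaks upstream of rpl-35 (signal value 393.5) and rpl-15 (signal value 381.0) followed. The remaining 5 of the 10 highest nuclear peaks were nearest to K12H4.5, Y17G9B.5, serp-1.1, F33H1.4 and Y39B6A.43, with signal values from 296.0 to 324.8. The Y17G9B.5 peak was also within 500 bp of a 5' end of rpl-20, a ribosomal protein gene. The rule fixed for naming took the 10 highest peaks, 7 of which were mitochondrial; the use of nuclear peaks was chosen after this was seen. The signal values were the authors', without a stated scaling.

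The replicates shared their strongest peaks. Peaks at rpl-3, tasp-1, cdc-48.1, rpl-35 and rpl-15 ranked between 5 and 14 in replicate 1 and between 2 and 14 in replicate 2. Of the 2141 highest peaks of replicate 1, 1325 (61.9%, exact 95% interval 59.79 to 63.95%) overlapped one of the 2141 highest of replicate 2 by at least 1 bp, against a mean of 2.02% over 100 random placements. The placements were uniform along each peak's chromosome and kept no preference for promoters. The contrast therefore does not separate LIN-13 binding from other signal common to both replicates. The overlapping share fell with rank: 95.4% for ranks 1 to 500, 71.6% for 501 to 1000, 50% for 1001 to 1500 and 37.4% for 1501 to 2141. Of the 2141 IDR peaks, 2138 overlapped a relaxed peak of replicate 1 and 2136 one of replicate 2. IDR peaks were selected on pooled signal and each relaxed list held 30000 peaks, so this overlap says little about agreement. Of 52 named genes with a peak (lin-35 was left out of this count), 45 had it within the 2141 highest peaks of both replicates. The genes act-5 and fbxa-99 had it in neither, and set-2, lin-28, act-2, srh-269 and fbxa-108 had it only in those of replicate 2.

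Across the 2133 IDR peaks with a relaxed peak in both replicates, the log10 signal values correlated with Pearson's r of 0.575 and Spearman's rho of 0.432. Over the 2114 nuclear ones r was 0.529 and rho 0.418. Peaks are not independent replicates, so no p-value was computed. The IDR peaks were those of highest pooled signal value, which was close to the sum of the 2 replicates' values (median ratio 0.998), so r and rho depend on that cut.

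**Figure D1:**
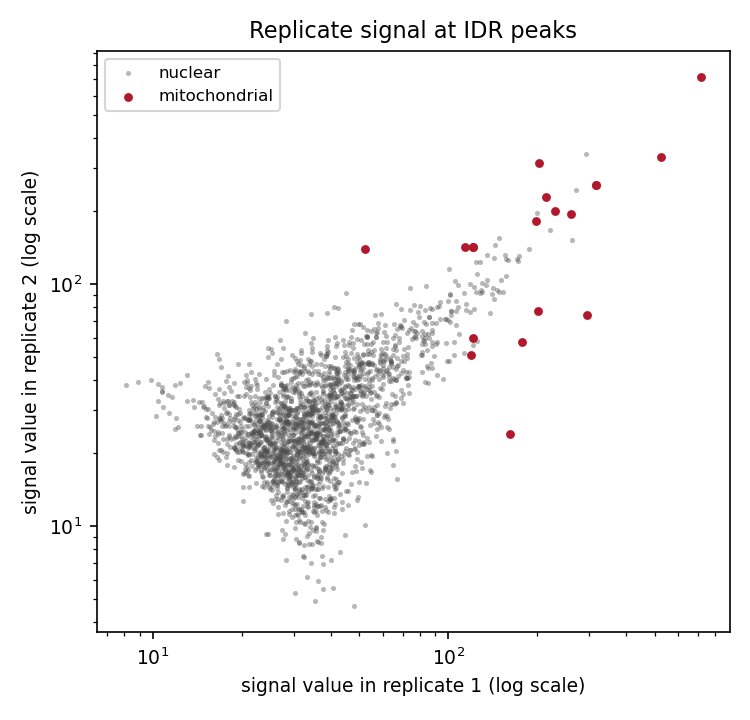
Signal value of the highest overlapping relaxed peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) at each IDR peak; grey points are nuclear and red points mitochondrial. Over the 2133 peaks r was 0.575, and the mitochondrial peaks lie mostly at the upper right.

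LIN-13 summits lay at promoters more often than the genome's composition gives. Of 2121 nuclear summits, 1131 (53.3%, exact 95% interval 51.2 to 55.5%) were within 500 bp of an annotated 5' end of a protein-coding transcript, against 23.1% of nuclear bases (exact binomial test, two-sided, p = 4.88e-199). The summits and bases outside these promoter windows were each put in the first class that held them. The order was coding exons, 5' UTRs, 3' UTRs, introns, exons of non-coding RNAs and pseudogenes, and intergenic. Exons, UTRs and introns inside the windows are therefore not in these counts. On that count coding exons held 27 summits (1.27% against 17.9% of bases), introns 329 (15.5% against 26.3%), 3' UTRs 37 (1.74% against 2.64%) and 5' UTRs 3 (0.141% against 0.186%). Exons of non-coding RNAs and pseudogenes held 108 summits (5.09% against 2.55%), and 486 (22.9% against 27.4%) were intergenic. The promoter share stayed above the 30.5% of relaxed peaks outside the IDR list (Fisher's exact test, two-sided, p = 3.68e-97).

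Soft-masked repeats held 373 summits (17.6%, exact 95% interval 15.99 to 19.27%), against 35.7% of nuclear bases (exact binomial test, two-sided, p = 1.03e-75) and 35.4% of relaxed peaks outside the IDR list.

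The chromosomes differed in the density of summits, from 12.5 per Mb on chromosome V to 31.8 per Mb on chromosome III. Autosome arms, the outer parts that make up 66.7% of each autosome's length, held 1118 of 1761 autosomal summits (63.5%, exact 95% interval 61.2 to 65.7%), against 66.7% of length (exact binomial test, two-sided, p = 0.00501). Relaxed peaks outside the IDR list had the same arm share of 63.5%, and against them no difference passed the test (Fisher's exact test, two-sided, p = 0.98). The X chromosome held 360 summits (16.97%, exact 95% interval 15.4 to 18.6%), against 17.7% of length (exact binomial test, two-sided, p = 0.409). The X share was below the genome's in the 2141 highest peaks of replicate 1 (15.4%, exact binomial p = 0.00525) and in the 4282 highest pooled peaks (16.17%, exact binomial p = 0.0101).

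**Figure D2:**
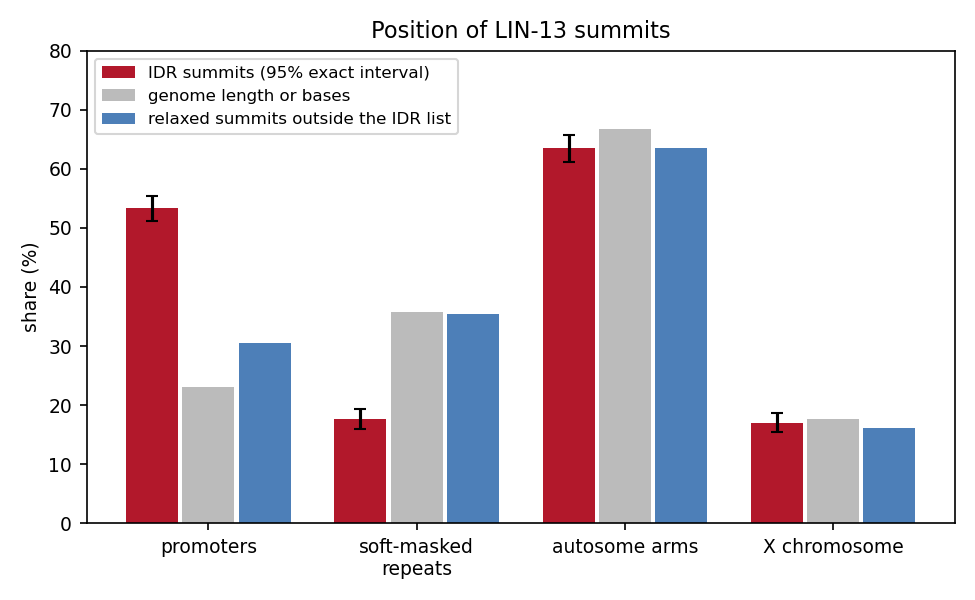
Shares (y axis, %) of IDR summits with exact 95% intervals (red), of genome length or bases (grey) and of relaxed summits outside the IDR list (blue) at promoters, on soft-masked repeats, in autosome arms and on X. Promoters hold 53.3% of IDR summits and repeats 17.6%.

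Promoter peaks were slightly stronger than the others. Their mean log10 signal value was 1.82 ± 0.185 (SD, n = 1131 peaks), against 1.78 ± 0.157 (SD, n = 990 peaks) elsewhere (permutation test, two-sided, adjusted p = 3e-05 over 3 comparisons; the unadjusted 1e-05 is the smallest that 100000 resamples can give). X and autosomes differed by -0.0012 (permutation test, adjusted p = 0.907), and arms and centres by 0.0048 (adjusted p = 0.862).

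Ribosomal protein genes had the highest share of bound genes of the 20 lists at 500 bp, though not at 200 bp: 58 of 78 (74.4%, exact 95% interval 63.2 to 83.6%) had a summit within 500 bp of a 5' end, against 6.73% of the other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 3.27e-49 over 20 lists). The strongest were rpl-3, rpl-35 and rpl-15. Within 200 bp, 9 of the 78 were bound (11.5% against 3.40%, Fisher's exact test, adjusted p = 0.00917), below synMuv B and DREAM (20%), stress response (16.7%) and cell cycle genes (13.9%). With summits at the 5' ends of 1 protein-coding gene only, a test chosen after seeing the data, 25 were bound (32.1% against 3.96%, Fisher's exact test, adjusted p = 2.6e-15). Among 19973 protein-coding genes, 1397 (6.99%) were bound in this sense.

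Genes of LIN-13's own class were bound more often than all others, a call that ended among genes with any relaxed summit at a 5' end. Of 20 synMuv B and DREAM genes, which repress cell cycle and germline genes in somatic cells, 7 were bound (35% against 6.97%, Fisher's exact test, adjusted p = 0.000794). Their highest peaks were at lin-54 (signal value 212.5), lin-9 (185.7) and lin-53 (109.7), which encode subunits of the MuvB core. The lin-54 peak was also within 500 bp of a 5' end of rpl-12, a ribosomal protein gene, and the lin-53 peak of nra-2. With summits at the 5' ends of 1 gene only, 4 of the 20 were bound (20% against 4.05%, Fisher's exact test, adjusted p = 0.026). Among genes with a relaxed summit, 7 of 17 were bound (41.2% against 17.9%, Fisher's exact test, adjusted p = 0.0858). A peak 168 bp from the 5' end of lin-35, the worm retinoblastoma gene, had a signal value of 82.8 and rank 451. Neither hpl-2, an HP1 homologue, nor lin-61 nor unc-119 had an IDR summit within 500 bp of a 5' end; their nearest relaxed summits ranked 29876, 6102 and 26069.

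Stress response genes (9 of 30, 30% against 6.96%, Fisher's exact test, adjusted p = 0.000485) included hsp-3, an endoplasmic reticulum chaperone (signal value 168.5), xbp-1, a transcription factor of the unfolded protein response (140.8), and hsp-1, an Hsp70 chaperone (129.2). Cell cycle and DNA replication genes (10 of 36, 27.8% against 6.96%, Fisher's exact test, adjusted p = 0.000485) included pcn-1, the sliding clamp of replication (89.3), mdf-2, a spindle checkpoint gene (75.0), and knl-1, a kinetochore gene (69.5). Small RNA pathway genes (8 of 32, 25% against 6.97%, Fisher's exact test, adjusted p = 0.00324) included mut-15 (signal value 100.1), rde-4 (68.6) and alg-2, an Argonaute gene (62.9). The small RNA call ended with replicate 1 alone (12.5% against 6.91%, Fisher's exact test, adjusted p = 0.506) and in the stronger part of the IDR list (9.38% against 3.94%, adjusted p = 0.291). It also ended at 200 bp (9.38% against 3.42%, Fisher's exact test, adjusted p = 0.174) and with summits at the 5' ends of 1 gene only (9.38% against 4.06%, adjusted p = 0.31). The share of other genes fell as well in the last 3 of these settings. The peaks named for mdf-2, mut-15 and rde-4 were shared with nduv-3, fib-1 and cox-14. In all, 18 of 52 named genes shared their peak with another protein-coding gene. The lin-35 peak was left out of this count. Non-coding genes near a peak were not counted as sharing it, here or with summits at the 5' ends of 1 gene only.

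Chemoreceptor, C-type lectin and F-box genes were bound less often than other genes. Chemoreceptor genes had 3 of 1272 bound (0.236% against 7.45%, Fisher's exact test, adjusted p = 1.09e-35), named sri-5, srh-16 and srh-269. C-type lectin genes had 1 of 240, clec-126 (0.417% against 7.07%, Fisher's exact test, adjusted p = 7.75e-06), and F-box genes 4 of 322 (1.24% against 7.09%, adjusted p = 1.17e-05), led by fbxb-85, fbxa-99 and fbxa-108. With replicate 1 alone, 2 of the 322 F-box genes were bound (0.621% against 7.02%, Fisher's exact test, adjusted p = 3.2e-07).

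The other 12 lists did not pass the adjusted test. Heterochromatin and histone methylation genes had 2 of 22 bound (met-1 and set-2), germ granule genes 3 of 28 (nos-3, car-1 and oma-2), meiosis genes 2 of 31 (brc-1 and syp-4) and histone genes 7 of 72 (led by his-37, his-67 and his-68). Vulval induction genes had 1 of 33 (egl-17), developmental timing and Hox genes 1 of 18 (lin-28), muscle genes 2 of 31 (unc-112 and act-2), neuron genes 1 of 34 (snb-1) and intestine genes 2 of 31 (asp-1 and act-5). Cuticle collagens had 6 of 176 (led by col-85, col-38 and col-71), nuclear hormone receptors 10 of 269 (led by nhr-47, nhr-35 and nhr-68, Fisher's exact test, adjusted p = 0.0667) and major sperm proteins 0 of 31 (exact 95% interval 0 to 11.2%). Nuclear hormone receptors passed as lower with replicate 2 alone (2.97% against 6.71%, Fisher's exact test, adjusted p = 0.0325) and in the 4282 highest pooled peaks (7.43% against 12.2%, adjusted p = 0.0321). Cuticle collagens (6.82%) and major sperm proteins (0%) also passed as lower in that list (both with a Fisher's exact test adjusted p of 0.0498). The peak named for col-38 was shared with rpl-5, a ribosomal protein gene.

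Among the 7793 genes with any relaxed summit at a 5' end, 4 lists passed instead of 8. Ribosomal protein genes (58 of 76, 76.3% against 17.4%, Fisher's exact test, adjusted p = 1.64e-27) and stress response genes (9 of 19, 47.4% against 17.9%, adjusted p = 0.0158) were higher. Only 83 of the 1272 chemoreceptor genes and 72 of the 322 F-box genes had a relaxed summit at a 5' end. Chemoreceptor genes (3 of 83, 3.61% against 18.1%, Fisher's exact test, adjusted p = 0.00138) and F-box genes (4 of 72, 5.56% against 18.04%, adjusted p = 0.0158) were lower. The calls ended there, on fewer genes, for synMuv B and DREAM genes (as given above), cell cycle genes (10 of 30, 33.3% against 17.9%, Fisher's exact test, adjusted p = 0.114), small RNA genes (8 of 25, 32% against 17.9%, adjusted p = 0.201) and C-type lectins (1 of 29, 3.45% against 17.98%, adjusted p = 0.114).

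**Figure D3:**
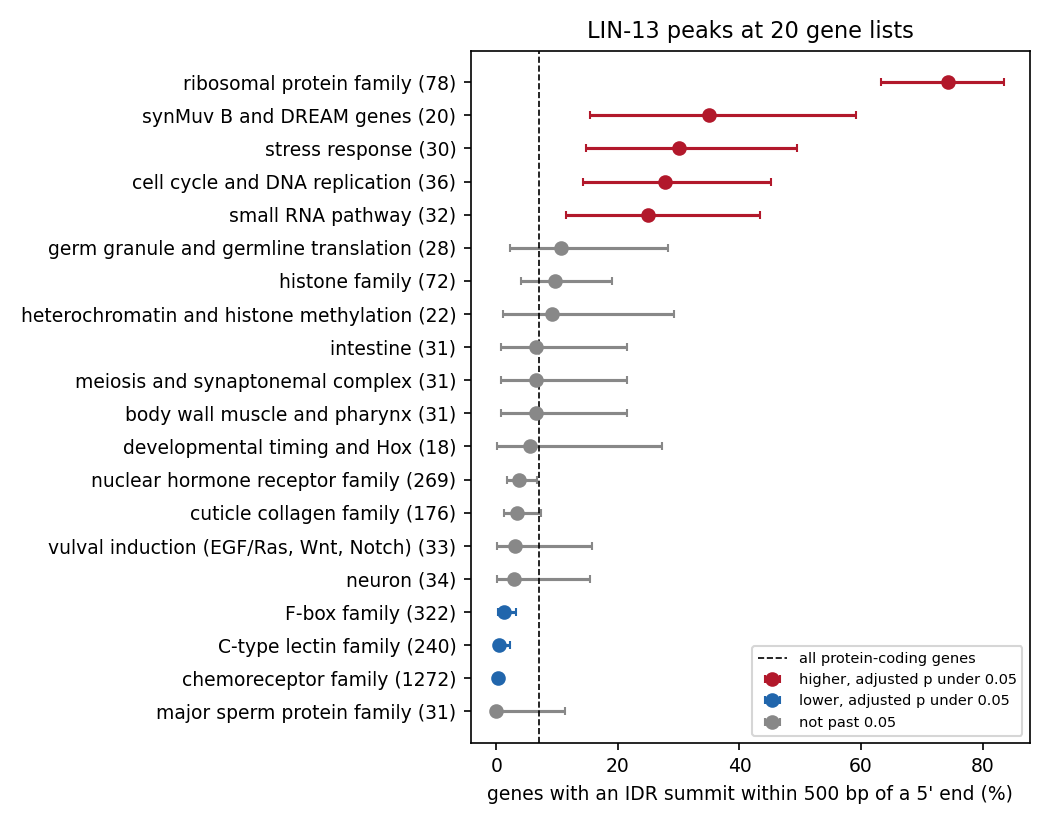
Share of each list's genes with an IDR summit within 500 bp of a 5' end (x axis, %), with exact 95% intervals and list sizes in parentheses; the dashed line is all protein-coding genes at 6.99%. Ribosomal protein genes stand at 74.4% and chemoreceptor genes at 0.236%.

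GAGA repeats were the motif that differed most between summits and the windows 1000 bp downstream. GAGAGAG was within 100 bp of 19.8% of summits, against 4.01% of these windows (exact McNemar test, two-sided, adjusted p = 1.87e-61 over 10 motifs). The E2F-like motif was at 16.8% against 9.10% (exact McNemar test, adjusted p = 7.54e-13), the SP1-like motif at 11.1% against 3.72% (adjusted p = 8.05e-21) and the E-box at 6.98% against 4.05% (adjusted p = 3.28e-05). Lower at summits were the CHR-like motif (51.3% against 60.8%, exact McNemar test, adjusted p = 1.97e-09), GATA (31.3% against 38.9%, adjusted p = 2.54e-07), the T-block (25.5% against 32.6%, adjusted p = 4.79e-07), the HSF-like motif (9.38% against 15.3%, adjusted p = 1.29e-08) and Hox-PBX (8.82% against 15.6%, adjusted p = 7.25e-11). AP-1 did not pass (2.12% against 1.41%, exact McNemar test, adjusted p = 0.101), but was higher with replicate 1 alone (2.41% against 1.42%, adjusted p = 0.0257) and in the 4282 highest pooled peaks (2.46% against 1.64%, adjusted p = 0.00968). In that longer list the GATA call ended (37.01% against 37.55%, exact McNemar test, adjusted p = 0.621).

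Matching on base composition ended most of these calls. Summit windows had a mean GC content of 43.8% and the downstream windows 37.0%. Against all relaxed peaks outside the IDR list 9 motifs passed. Against relaxed peaks matched on GC content, a comparison chosen after seeing the data, only 3 motifs passed: GAGA (19.8% against 12.02%, Fisher's exact test, adjusted p = 3.63e-11), the E2F-like motif (16.8% against 12.97%, adjusted p = 0.00183) and the CHR-like motif, which turned from lower to higher (51.3% against 45.9%, adjusted p = 0.00183). The matched windows were relaxed peaks and may include weaker LIN-13 sites, so the ended calls cannot be put down to base composition alone.

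**Figure D4:**
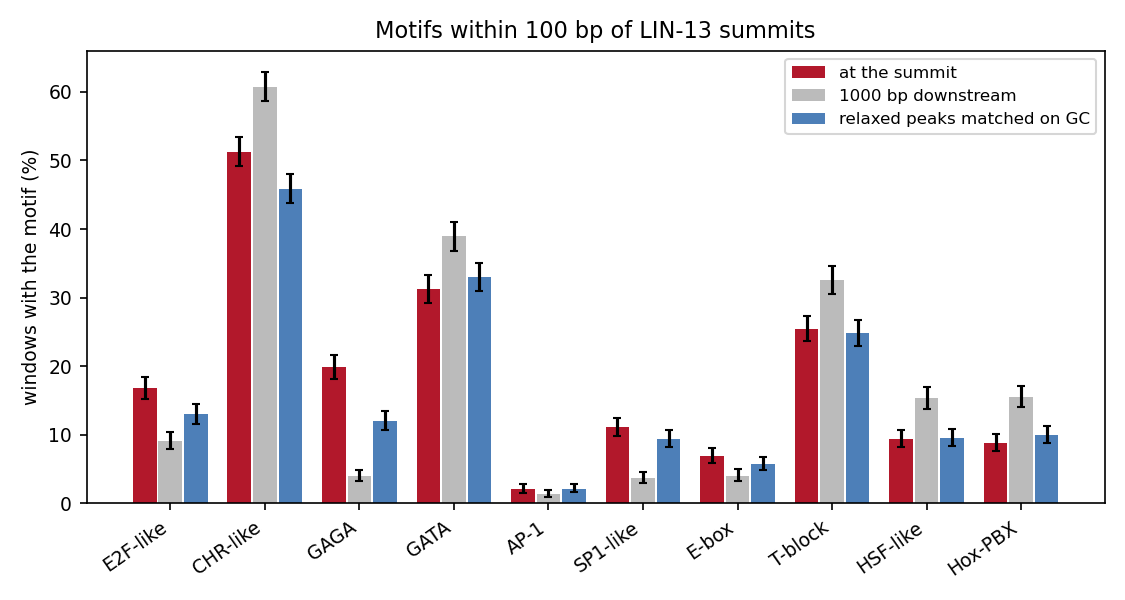
Share of windows holding each motif (y axis, %), with exact 95% intervals, at IDR summits (red), 1000 bp downstream (grey) and at relaxed peaks matched on GC content (blue). GAGA is at 19.8% of summits, 4.01% downstream and 12.02% of the matched peaks.

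The lin-13 locus held 6 IDR summits within the gene and 20 kb on either side (chromosome III, 7680338 to 7729491, ce11). As many were found in 0.95% of windows of the same length over the nuclear genome, where the median was 1. The highest peak (7710150 to 7710355, signal value 285.6, rank 22) was intergenic, with its summit 782 bp upstream of the 5' end of lin-13, a gene on the minus strand from 7700338 to 7709491. The others lay upstream of C03B8.3, upstream of ncl-1 and in introns of ncl-1. No relaxed summit of the pooled list fell inside lin-13 itself, and all 19 of the window lay at higher coordinates than its 5' end.

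**Figure D5:**
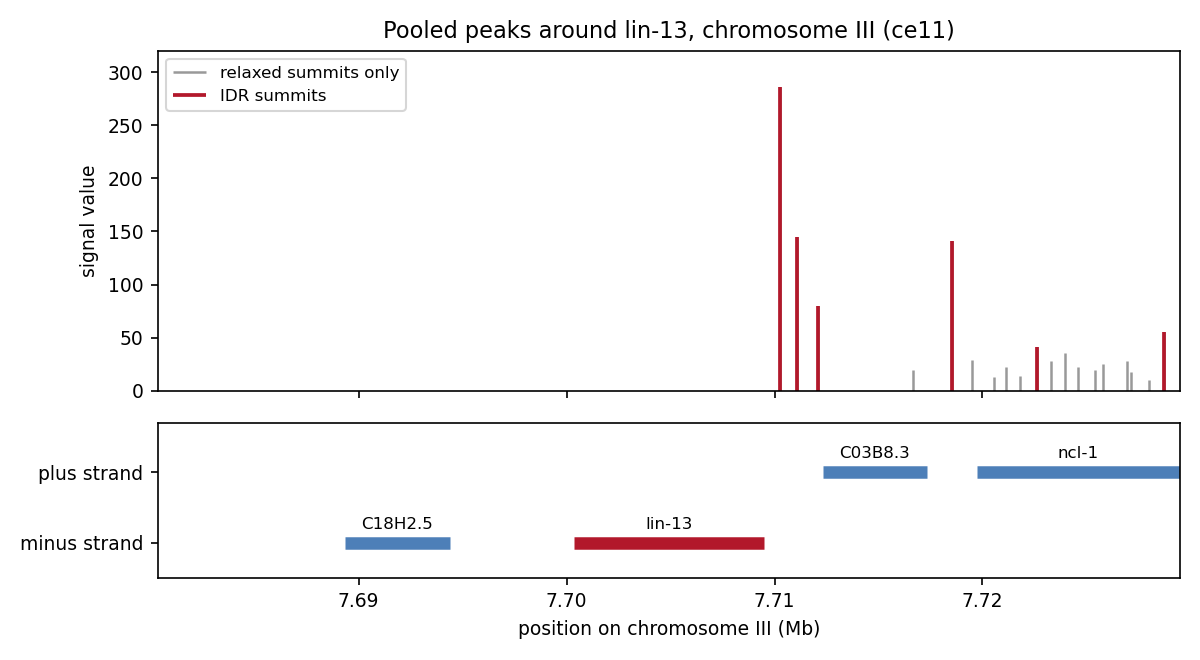
Signal values (y axis) of pooled summits along chromosome III in Mb (x axis, ce11), with IDR summits in red and other relaxed summits in grey, above the protein-coding genes by strand. All 19 summits lie to the right of lin-13.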

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

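Mitochondrial DNA, left out of the position, gene and motif tests, held 20 IDR peaks that covered 44.9% of its 13794 bp, against 0.68% of the nuclear genome, and 7 of the 10 highest peaks, with signal values up to 1428.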

How the results depend on the processing

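The tests matched on GC content, thinned to 1 summit per 10 kb or on summits at the 5' ends of 1 gene only were chosen after seeing the data. No paired analysis was possible because there is 1 group. Arms on ce10 were not run. Depth is unknown, so its effect on the lists could not be measured. The promoter and repeat shares kept their direction and side of the threshold under every alternative run, but the promoter share was 29.2% against 9.97% of bases at 200 bp and the repeat share 9.85% against 30.4% for the wider repeat window. The ce10 list held 2114 peaks.

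The replicate overlap of 61.9% was 56.1% with summits within 100 bp, 58.0% with 50% of both peaks and 59.4% for the 4282 highest. The correlation was -0.32 just below the IDR peaks, down to rank 4282. Those peaks were a band of pooled signal values from 27.5 to 40.1, close to the replicates' sum (median ratio 0.993), so the sign follows from the selection and does not measure agreement. The X share was between 15.4 and 16.8% in single replicates and 16.17% in the looser list. It was 16.97% against 16.09% of relaxed peaks and 18.2% at 1 summit per 10 kb, both above the background. The arm share of 63.5% equalled that of relaxed peaks. X minus autosome signal, -0.0012, turned positive, with 0.0084 to 0.013 in single replicates, 0.024 stricter, 0.010 looser and 0.0025 on ce10; none passed. The count of lists past 0.05 fell to 4 with the relaxed gene background, and motifs fell to 3 with GC matching, while AP-1 (2.12%), CHR-like (51.3%) and the T-block (25.5%) changed direction. AP-1 (2.12%) also did so against all relaxed peaks. The locus held 10 summits in the looser list. The cause was not tested except where stated.

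Of 200 list values 165 were the same, 8 lost and 4 gained the call (nuclear hormone receptors in 2 settings, collagens and major sperm proteins), and 23 changed direction, all in lists that did not pass. Over both single replicates the ranges were meiosis 9.68 to 16.13%, timing and Hox 0 to 11.1%, muscle 3.23 to 9.68% and heterochromatin 4.55 to 13.6%. The looser list gave meiosis 12.9%, timing 16.7% and intestine 19.4%; 200 bp gave meiosis 6.45% and timing 5.56%; 1000 bp gave meiosis, muscle and intestine 9.68% each. The relaxed background gave heterochromatin 12.5%. Gene bodies gave vulval induction 12.1%, timing 22.2%, muscle 9.68% and intestine 16.13%. Thinning gave timing 5.56% and intestine 6.45%, and summits at the 5' ends of 1 gene only gave timing 5.56% and muscle and intestine 6.45% each. Of the named peaks' ranks in single replicates, lin-35 left out, 9 fell outside the 2141 highest and 95 did not.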

Other observations

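The gene classes in the next paragraphs were chosen after the values were seen, as were the tests of peak calling in repeats and of transgene copies. Several classes of non-coding RNA genes lay near LIN-13 summits more often than near relaxed peaks. tRNA genes lay within 200 bp of 196 nuclear summits (9.24%), against 0.272% of bases and 0.99% of relaxed peaks outside the IDR list (Fisher's exact test, adjusted p = 3.66e-99 over 10 classes). snoRNA genes lay near 83 summits (3.91% against 0.399% of relaxed peaks, adjusted p = 2.46e-43) and snRNA genes near 29 (1.37% against 0.163%, adjusted p = 1.56e-14). Genes annotated as ncRNA lay near 383 (18.1% against 5.67%, Fisher's exact test, adjusted p = 7.52e-79) and miRNA genes near 12 (0.566% against 0.174%, adjusted p = 0.00159). piRNA genes lay near 14 summits, below the relaxed peaks (0.66% against 3.07%, adjusted p = 1.88e-13). Pseudogenes, lincRNAs, antisense RNAs and rRNA genes did not pass against relaxed peaks, and rRNA genes lay near 0 of 2121 summits.

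Of 6 further protein families, 4 passed both against all genes and among genes with a relaxed summit. The families were matched by gene name only, so members with other names were missed and unrelated genes with a matching name may be included. Proteasome subunits had 17 of 33 genes bound (51.5% against 6.92%, Fisher's exact test, adjusted p = 3.78e-11), led by rpn-3, rpn-9 and rpn-11. Respiratory chain and ATP synthase genes had 18 of 38 (47.4%), led by cox-5B, cox-5A and cox-6B, with a signal value of 285.9 at cox-5B. Translation factors had 16 of 39 (41.0%), led by iff-2, eef-1A.1 and eef-1B.1, and spliceosomal genes 10 of 31 (32.3%), led by prp-8. Aminoacyl-tRNA synthetases (5 of 32) and mitochondrial ribosomal proteins (7 of 70) did not pass. For these families, peaks shared with another gene were not set aside.

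Summits at ribosomal protein and tRNA genes were weighed first, since strongly transcribed genes can gather signal without specific binding. Signal spread over the annotated bodies of ribosomal protein genes was argued against, since 2 of 58 summits lay inside the gene (3.45%, exact 95% interval 0.42 to 11.9%). Sequence transcribed upstream of a trans-spliced 5' end, or in a neighbouring gene, was not counted as inside. Signal from transcription there stays open. Reads shared between tRNA copies stay open: 83.1% of the 36-mers of peaks near tRNA genes occurred once in the genome, between the bounds of 50% and 90% set in advance, against 96.8% in all IDR peaks and 15.3% in the tRNA genes themselves. The read length is not given in the sources used here. Open chromatin at active promoters was not tested, because no untagged or input profile was analysed here, and no biological explanation was tested in 1 group.

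The low share of summits on soft-masked repeats was weighed against mappability and peak calling. Positions whose 36-mer occurs once were soft-masked in 34.1% of cases, above the upper bound of 19.3% for IDR summits, which argues against unmappable repeats as the whole cause. Relaxed summits outside the IDR list were soft-masked in 35.4% of cases, so calling itself reached repeats. These summits include background, and their share was near the 35.7% of nuclear bases. The test therefore cannot show whether strong signal in repeats was lost in calling. Base composition and the position of promoters outside repeats were not tested, and no biological explanation was tested.

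The lin-13 locus was weighed against extra copies in the transgene. IDR peaks are selected on signal, so only the 13 relaxed peaks outside the IDR list were used. Their median signal value of 22.2 was above 16.75, the 95th percentile of windows of the same length with 7 to 19 such peaks. The lists were called with a control library, and whether it carried the transgene was not examined here. If it did, extra copies need not raise signal, so the test cannot decide and this explanation stays open. All 19 relaxed summits of the window lay upstream of the gene, and a stretch of 37558 bp that holds lin-13 had no relaxed peak, the 184th longest of 27524 such stretches. The reference genome's unc-119 gene had a nearest relaxed peak of rank 26069. The transgene's rescue marker is unc-119, but whether reads of the marker copy map to that gene was not examined. The transgene's extent and copy number were not used here.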
